A study of Danio rerio with 56 samples.

How the data were processed

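RNA was measured in unfertilised eggs and in embryos at 10 hours post fertilisation (hpf) of the 5D zebrafish strain. The parents had eaten flakes treated with acetone (control) or with benzo[a]pyrene (BaP), a polycyclic aromatic hydrocarbon, at 25 µg per g of fish (1250 µg per g of food) for 21 days from an age of 120 days. Per the labels, libraries were made from ribosome-depleted total RNA and sequenced as read pairs. The 24 RNA libraries form 6 groups of 4: control eggs, eggs of BaP-fed mothers, and embryos of 4 crosses (both parents control, only the mother BaP-fed, only the father BaP-fed, both BaP-fed). The group labelled only as BaP at 10 hpf was read as both parents BaP-fed, because the other 3 crosses of the cross-over design carry labels of their own. The 32 bisulfite samples were not analysed here. The labels do not say which tank or spawning a replicate came from, so every p-value measures the spread between these libraries only.

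Per the submitters' processing notes, the reads were handled with FastQC, Salmon and DESeq2 and the build was GRCz11. Their versions are not given in the sources used here. Per the file headers, each deposited table gives a length, an effective length, a TPM value and an estimated count of reads (expected counts, which need not be whole) for each row. Each of the 24 tables held the same 57192 rows. The rows carry versioned Ensembl transcript identifiers, and their lengths were whole and identical in all libraries, so the values were taken as values per transcript although the tables are named for genes. The deposited TPM values summed to 1000000 in each library and were not used for tests. The reference tables in use here pair gene identifiers with symbols, and 0 of the 57192 rows matched them. No gene name or coordinate is therefore given, and at most 2 transcripts with higher and 2 with lower values are named per comparison by the rule given here, besides 1 transcript that alone makes up a count and was also lower with BaP-fed fathers than in controls. The 32 gene lists fixed before the data were examined, their tests, the preset named genes, the shares of mitochondrial and ribosomal RNA and the list-based developmental score could not be computed.

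Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3). TMM factors, filterByExpr by group, glmQLFit with robust=TRUE and glmQLFTest were used, with Benjamini-Hochberg adjustment over the transcripts tested. A transcript was called at an adjusted p under 0.05. Eggs were fitted alone (8 libraries), and all embryo contrasts came from 1 fit of the 16 embryo libraries with a mean per cross. These designs were fixed before the data were examined. Standard errors of log2 fold changes were derived from the fold change and the F statistic. Isoforms of a gene share reads, and salmon divides such reads by estimate, so a fall of 1 transcript can reflect a different division of reads. Library totals ran from 26010776 to 55044612 estimated counts. Counting intervals and floors cover counting error only, and a group with no counts was set to a floor of 3 counts over the group.

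Data were simulated with the means, library sizes and spread of the real libraries. The 200 changed transcripts had a mean of at least 2 CPM, so recovery of less abundant ones was not measured. In the egg design (29023 transcripts) edgeR recovered 30 of 100 transcripts changed 2-fold and 70 of 100 changed 4-fold. In the design for BaP-fed fathers (30894 transcripts) it recovered 62 and 92 of 100. In the interaction design it recovered 32 and 78 of 100. Of the calls edgeR made, 3.85%, 3.75% and 6.78% were false in these 3 simulations. DESeq2 1.42.0, used as an alternative, recovered 64 and 90 of 100 in the egg design with 37.9% false calls, 76 and 99 of 100 in the father design with 34.2% false calls, and 45 and 87 of 100 in the interaction design with 32.0% false calls. Each simulation was run once, with the spread estimated by edgeR and only transcripts kept by its filter. The DESeq2 counts given below come from all 57192 rows, so these false-call rates need not hold for them.

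Log2 CPM used a prior count of 2. Named transcripts were those past the threshold with a mean of at least 2 CPM and no overlap between the 2 groups, by largest fold change. Where fewer than 3 passed in a direction, those of smallest p that met the other conditions were taken. The parts of this rule that need gene symbols could not be applied. For the factorial contrasts, the transcript of smallest adjusted p among those with a mean of at least 2 CPM was named for the maternal effect and the interaction, and a count of 1 was named in full. Egg-enriched transcripts (3017) and embryo-enriched transcripts (3275) differed by at least 3 on the log2 scale between the means of all eggs and all embryos and had at least 2 CPM in the higher stage. These sets, the class of transcripts longer than 5000 bases and the tests on them were chosen after seeing the data. Shares and totals were compared by exact two-sided permutation tests, adjusted over 24 tests. The developmental position of a library is its projection on the axis from control eggs (0) to control embryos (1) over 22530 transcripts.

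The alternatives were other normalization factors, other low-count filters, an effective-length offset, a non-robust dispersion, a replicate block, DESeq2, fits of only the 2 groups compared and leaving out each replicate. Those added after seeing the data were whole-count transcripts only (within 0.001 in every library), removal of a trend on length, leaving out 2 libraries and 2 other forms of the developmental axis. Every replicate pair differed far beyond counting noise (chi-square per degree of freedom of 14.2 or more), so no library was taken as a duplicate.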

Results

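Eggs and 10 hpf zebrafish embryos were profiled to ask whether BaP in the diet of mothers, fathers or both changed the RNA of eggs and offspring. Totals were 36548517 to 55044612 estimated counts in the 8 egg libraries and 26010776 to 38130629 in the 16 embryo libraries. Between 36132 and 38389 transcripts had a count in a library. Across transcripts, which are not independent replicates, log2 CPM correlated at a median of 0.944 between egg libraries, 0.952 between embryo libraries and 0.362 between eggs and embryos.

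Control embryos were first compared with control eggs as a check of the stages. Of 30650 transcripts tested, 11416 were higher and 11799 lower in embryos (edgeR quasi-likelihood test). Egg-enriched transcripts took 21.5% to 22.4% of the counts of control eggs and 0.443% to 0.478% of those of control embryos. Embryo-enriched transcripts took 1.15% to 1.22% in control eggs and 22.7% to 23.2% in control embryos. These sets were defined on all 24 libraries, so their contrast between stages holds by construction. The median log2 fold change of transcripts of at least 2 CPM was -0.15 with TMM factors, -0.10 with RLE factors and 0.11 with upper-quartile factors, and changes are given relative to the TMM scale.

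Eggs of BaP-fed mothers were compared with control eggs to ask whether the mothers' diet changed egg RNA. ENSDART00000170689.2 had 11.2 ± 1.05 CPM with BaP and 2.3 ± 1.39 CPM in controls (SD, n = 4), a log2 fold change of 2.29 ± 0.40 (SE) that did not pass (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.92). ENSDART00000105933.4 had 9.71 ± 3.68 and 2.84 ± 0.645 CPM (edgeR adjusted p = 0.962). ENSDART00000169072.2 had 131 ± 5.43 and 160 ± 5.01 CPM, and ENSDART00000133850.2 had 42.9 ± 2.39 and 55.4 ± 1.32 CPM, and neither passed in edgeR. Embryo-enriched transcripts took 1.3% ± 0.0746 of the counts in BaP eggs and 1.2% ± 0.0348 in control eggs (SD, n = 4; two-sided exact permutation p = 0.0286, the smallest this design can give, exact permutation p adjusted over 24 tests 0.137), so this share did not pass after adjustment. None of 29023 transcripts passed in edgeR, with 1044 at an unadjusted p under 0.05 against 1451 by chance, and DESeq2 called 109 (48 higher, 61 lower). All 4 transcripts named here were among the 109 (DESeq2 adjusted p from 1.47e-05 to 0.000167). In the simulation of the egg design, 37.9% of the DESeq2 calls were false. Of those 109, 50 (45.9%) had a count of 0 in at least 1 egg library, against 10.3% of the transcripts tested. DESeq2 was run on all 57192 rows without the low-count filter, so these 2 shares may rest on unlike sets of transcripts. Groups did not overlap for 2.7% of the transcripts, where chance gives 2.86%. The edgeR count became 2 without control replicate 3, 2 without control replicate 4 and 1 without BaP replicate 4.

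Embryos of a BaP-fed mother and a control father were compared with control embryos. ENSDART00000079201.6 had 24.5 ± 2.06 CPM in these embryos and 13.1 ± 1.09 CPM in controls (SD, n = 4; edgeR adjusted p = 0.879), and ENSDART00000162459.2 had 168 ± 7.84 and 131 ± 2.83 CPM (edgeR adjusted p = 0.879). ENSDART00000052322.5 had 11.4 ± 1.83 and 18.9 ± 2.33 CPM, and ENSDART00000159815.3 had 7.4 ± 1.51 and 12.3 ± 0.775 CPM, and neither passed. Egg-enriched transcripts had a median log2 fold change of 0.09, and 58.3% of 2216 tested were above 0, with a median of 0.02 without mother replicate 1. Their share of the counts was 0.491% ± 0.0478 in this cross and 0.463% ± 0.017 in controls (two-sided exact permutation p = 0.40, adjusted over 24 tests 0.738). None of 30894 transcripts passed in edgeR, with 1291 at an unadjusted p under 0.05 against 1545 by chance, and DESeq2 called 88. Groups did not overlap for 3.62% of the transcripts, where chance gives 2.86%. Without control replicate 3 the edgeR count was 1, and a fit of only the 8 libraries of the 2 groups called 4, with ENSDART00000079201.6 past the threshold (edgeR adjusted p = 0.0475).

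Embryos of a BaP-fed father and a control mother had 128 transcripts lower and 3 higher than control embryos among 30894 tested. The 128 had a median log2 fold change of -0.73, with 10th and 90th percentiles of -1.06 and -0.53. Of them, 114 (89.1%) were higher in control embryos than in control eggs, against 47.6% of the transcripts of at least 2 CPM. Both comparisons use the same control embryo libraries, which raises this share, and no value without an effect was computed for it. Their median length was 4855 bases, against 2194 for transcripts of at least 2 CPM. Estimated counts were whole in all 16 libraries for 2 of the 128 (1.56%), against 19.5% of the transcripts of at least 2 CPM. ENSDART00000180271.1 (8615 bases) fell from 9.71 ± 0.999 to 2.3 ± 1.06 CPM (SD, n = 4), a log2 fold change of -2.08 ± 0.35 (SE, edgeR adjusted p = 0.0188). ENSDART00000059021.7 fell from 3.45 ± 0.241 to 1.53 ± 0.328 CPM (log2 fold change -1.18 ± 0.21, edgeR adjusted p = 0.0205). ENSDART00000192028.1 rose from 9.94 ± 1.34 to 18.7 ± 5.68 CPM (log2 fold change 0.91 ± 0.18, edgeR adjusted p = 0.0445). ENSDART00000039466.5 rose from 7.89 ± 0.692 to 13.9 ± 2.04 CPM (log2 fold change 0.82 ± 0.16, edgeR adjusted p = 0.0408). The test was the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, and DESeq2 called 828 (626 lower, 202 higher), including all 131. Groups did not overlap for 7.76% of the transcripts, where chance gives 2.86%. In a fit of only the 8 libraries of the 2 groups 57 were called (20 higher, 37 lower, 32 of them among the 131), and none of the 4 named transcripts passed (edgeR adjusted p from 0.0519 to 0.151). The count was 77 without a filter, 223 with a stricter one and 69 with a replicate block. It was 86 with a trend on length removed and 1 over transcripts with whole counts alone, these 2 chosen after seeing the data. Neither higher transcript passed without a filter or with the length trend removed (edgeR adjusted p from 0.0562 to 0.0625). The 131 calls became 85, 2, 69 and 4 without control replicates 1, 2, 3 and 4, and 2 and 31 without father replicates 1 and 2. The call of ENSDART00000192028.1 ended without any 1 of the 8 libraries, that of ENSDART00000039466.5 without any control replicate or father replicate 1 or 2, that of ENSDART00000059021.7 without control replicate 2, 3 or 4 or father replicate 1 or 2, and that of ENSDART00000180271.1 without control replicate 2 or 4 or father replicate 1.

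**Figure D1:**
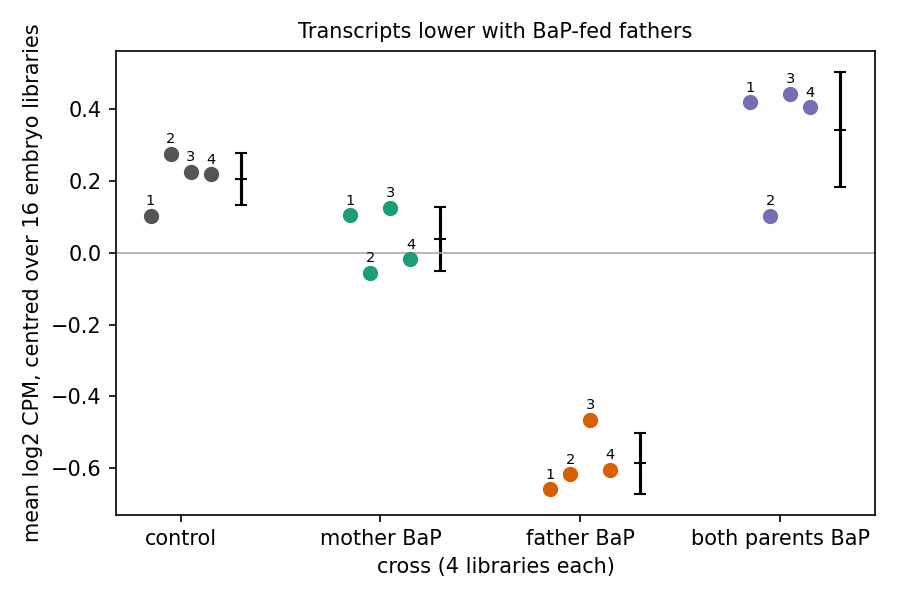
Mean log2 CPM of the 128 transcripts called lower in embryos with only the father BaP-fed, centred over the 16 embryo libraries, for the 4 libraries of each cross (points, numbered by replicate) with their mean and SD (bar). The transcripts were chosen on the father and control libraries, and the 4 father libraries lie between -0.66 and -0.46, below all other embryo libraries.

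Egg-enriched transcripts had a median log2 fold change of 0.36 in embryos of BaP-fed fathers, and 75.4% of 2216 tested were above 0. Their share of the counts was 0.587% ± 0.0749, against 0.463% ± 0.017 in controls (SD, n = 4; two-sided exact permutation p = 0.0286). Transcripts longer than 5000 bases took 14.6% ± 0.298 and 16.05% ± 0.373 of the counts (two-sided exact permutation p = 0.0286). Fewer transcripts had a count, 36411 ± 222 against 37217 ± 232 (two-sided exact permutation p = 0.0286). Each of these 3 values is the smallest p the design can give, and none passed after adjustment over 24 tests (exact permutation p adjusted to 0.137).

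Embryos of 2 BaP-fed parents had 1 transcript higher than control embryos. ENSDART00000140371.2 rose from 14.4 ± 1.59 to 40.1 ± 10.95 CPM (SD, n = 4), a log2 fold change of 1.48 ± 0.18 (SE, edgeR adjusted p = 0.0144). It stood at 23.1 ± 3.81 CPM with only the mother BaP-fed and 15.9 ± 1.99 CPM with only the father BaP-fed. ENSDART00000100974.5 (13.0 ± 1.07 against 7.12 ± 1.36 CPM), ENSDART00000098010.2 (23.6 ± 2.83 against 36.3 ± 3.81 CPM) and ENSDART00000145652.3 (2.18 ± 0.373 against 5.82 ± 1.58 CPM) did not pass. The 128 transcripts lower with only the father BaP-fed had a median log2 fold change of 0.18 in this cross and -0.15 with only the mother BaP-fed. They were chosen as lower than the same control libraries, which pushes both medians below 0, so the negative one is no evidence of a change. Egg-enriched transcripts had a median log2 fold change of 0.42, and 75.2% of 2216 tested were above 0, but without both-parents replicate 2 the median was 0.07 and 55.1% were above 0. Their share was 0.663% ± 0.338 (two-sided exact permutation p = 0.114, adjusted over 24 tests 0.457), with 1.17% in replicate 2. The difference in this share from controls was 0.2 percentage points with replicate 2 and 0.032 without it, and without replicate 4 it was 0.263 (exact permutation p = 0.0286). A count was found for 37661 ± 67.2 transcripts, against 37217 ± 232 in controls (two-sided exact permutation p = 0.0286, adjusted 0.137). In edgeR 3206 transcripts had an unadjusted p under 0.05 against 1545 by chance, and DESeq2 called 284. Groups did not overlap for 5.31% of the transcripts, where chance gives 2.86%. A fit of only the 8 libraries of the 2 groups called 3 other transcripts, all higher, and ENSDART00000140371.2 did not pass there (edgeR adjusted p = 0.149). The call of ENSDART00000140371.2 ended without control replicate 1, 3 or 4, and the count was 0 without control replicate 1 or 4 and 2 without both-parents replicate 2 or 3.

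**Figure D2:**
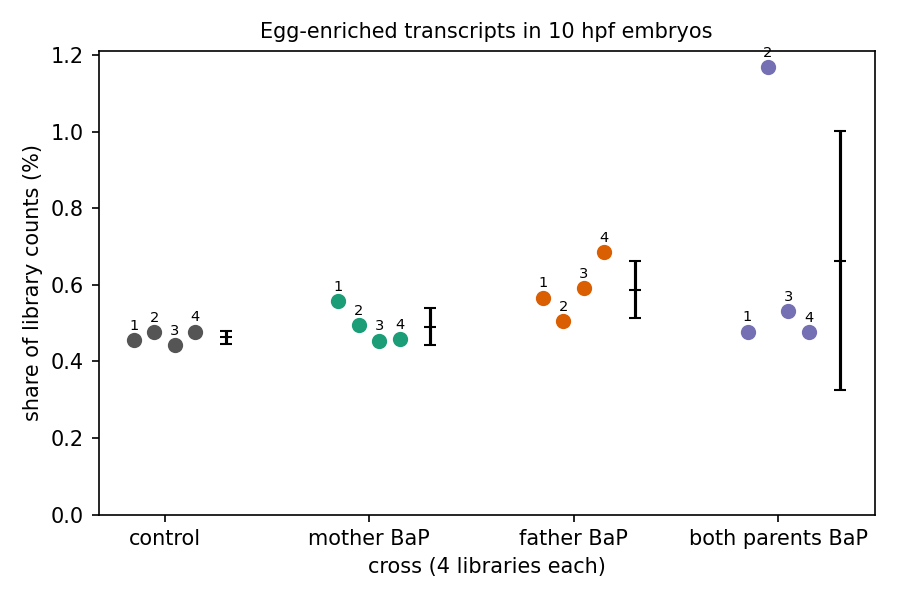
Share of library counts (percent) in the 3017 egg-enriched transcripts for the 4 libraries of each embryo cross (points, numbered by replicate) with their mean and SD (bar). Both-parents replicate 2 stands at 1.17%, and the other libraries lie between 0.443% and 0.686%.

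The cross-over design allowed the effect of each parent, and whether it depended on the other, to be tested. The interaction gave 278 calls in edgeR, 254 positive and 24 negative, and DESeq2 called 1067 (726 positive, 341 negative). Among the 254 were 119 of the 128 transcripts lower with only the father BaP-fed. The 2 tests share the father and control libraries, which raises this overlap, and no value without an effect was computed for it. ENSDART00000189361.1 stood at 10.6 ± 1.16 CPM in controls, 9.55 ± 0.899 with only the mother, 5.31 ± 0.492 with only the father and 12.9 ± 1.26 with both parents BaP-fed (SD, n = 4; interaction on the log2 scale 1.43 ± 0.17, edgeR adjusted p = 0.0052). The mother's effect, averaged over both kinds of father, gave 61 calls (34 higher, 27 lower), ENSDART00000140371.2 among the higher (log2 fold change 1.01 ± 0.12, edgeR adjusted p = 0.010). This average sets the mother and both-parents crosses against the control and father crosses. A fall with only the father BaP-fed therefore also counts as higher, so the 61 cannot be read as the mother's effect alone. Of 30 higher calls of at least 2 CPM, 15 were longer than 5000 bases, against 1 of 27 lower calls. Of 240 positive interaction calls of at least 2 CPM, 111 were, against 1 of 24 negative calls and 13.6% of the transcripts of at least 2 CPM tested. With a trend on length removed, an alternative chosen after seeing the data, the maternal count was 15 and the interaction count 185. With a replicate block they were 6 and 144. Without a filter they were 15 and 151, with a stricter filter the maternal count was 211, and the interaction count was 2 over transcripts with whole counts alone, also chosen after seeing the data. The father's effect, averaged over both kinds of mother, gave 1 call, ENSDART00000187324.1. With a replicate block it gave 0 in edgeR, with 1735 at an unadjusted p under 0.05. ENSDART00000187324.1 was also the 1 call between the 2 crosses with a single BaP-fed parent. It had no count with only the father BaP-fed, 1.72 ± 0.728 CPM in controls, 2.16 ± 0.709 with only the mother and 2.16 ± 0.686 with both parents BaP-fed. With a mean under 2 CPM, it also had the smallest adjusted p of the maternal effect (edgeR adjusted p = 0.00308) and of the interaction (edgeR adjusted p = 0.0052, shared with ENSDART00000189361.1). It was at least 73.6-fold lower than in controls, against a floor of 3 counts over the group (edgeR adjusted p = 0.00121).

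These factorial counts moved with single libraries. The interaction count was 169, 92, 175 and 132 without control replicates 1 to 4, 167, 90, 154 and 113 without mother replicates 1 to 4, 99, 127 and 153 without father replicates 1, 2 and 4, and 101, 422, 128 and 122 without both-parents replicates 1 to 4. The maternal count was 11, 24, 5 and 19 without control replicates 1 to 4, 2, 9, 3 and 9 without mother replicates 1 to 4, 3 and 18 without father replicates 1 and 4, and 5, 207, 102 and 3 without both-parents replicates 1 to 4. The paternal count was 2 without control replicate 3 or 4, mother replicate 4 or both-parents replicate 2. The count between single-parent crosses was 3 without mother replicate 4 or father replicate 2 and 18 without father replicate 3.

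Fold changes in eggs were set against those in embryos to ask whether differences in eggs were seen again. Across 24846 transcripts, which are not independent replicates, Pearson's r was 0.0931 (Spearman 0.108) with embryos of BaP-fed mothers, -0.0101 (Spearman -0.0225) with BaP-fed fathers and 0.0831 (Spearman 0.0611) with both. Regrouping the 8 egg libraries gave a value as far from 0 in 3, 31 and 8 of 35 splits, so none of the 3 passed. Without control egg replicate 4 the values for mothers and for both parents passed (0.115 and 0.121, exact permutation p = 0.0286 for each), as did that for mothers without control embryo replicate 4 (0.113, exact permutation p = 0.0286). Without control embryo replicate 3 they were 0.0603 and 0.0542, and without control egg replicate 1 that for both parents was 0.0387. Fold changes of the crosses, all against the same controls, correlated at 0.455 (mother and father), 0.551 (mother and both) and 0.419 (father and both), where simulated unchanged groups gave 0.498 ± 0.011 (SD of 20 simulations). The covariances were 0.171, 0.202 and 0.174, against 0.141 simulated. With the controls split in 3 ways, r was 0.0075 to 0.035, 0.0665 to 0.0943 and 0.0119 to 0.0381. With 1 edgeR call for both parents and fewer for mothers, an overlap of calls between crosses could not be assessed.

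On the axis from control eggs to control embryos, embryos stood at 0.952 ± 0.0188 with BaP-fed fathers, 0.958 ± 0.0579 with both parents and 0.983 ± 0.0158 with BaP-fed mothers, against 1 ± 0.00397 for controls (SD, n = 4; two-sided exact permutation p = 0.0286, 0.0286 and 0.0857, adjusted over 3 crosses 0.0429, 0.0429 and 0.0857). Both-parents replicate 2 stood at 0.872 and the other 3 at 0.978 to 0.992, and without it the difference went from -0.0419 to -0.0131. For both parents the test no longer passed without control replicate 1 (-0.0448), 2 (-0.0469), 3 (-0.0425) or 4 (-0.0446). Each of these differences was further from 0 than the -0.0419 with all libraries, so a smaller difference did not end the pass. For mothers the test passed without mother replicate 3 (-0.0221). The axis is drawn from the control libraries themselves, which places other groups lower. With an axis from all 24 libraries, chosen after seeing the data, the differences were -0.0387, -0.0325 and -0.0078 (two-sided exact permutation p = 0.0286, 0.257 and 0.486, adjusted 0.0857, 0.386 and 0.486), and none passed after adjustment. Over all transcripts with a count, also chosen after seeing the data, they were -0.0698, -0.0519 and -0.0342 on the axis from control libraries, and each passed (two-sided exact permutation p = 0.0286, adjusted 0.0286).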

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

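The 3 tests on the transcripts lower with only the father BaP-fed were chosen only after the results were seen. Among 74 groups of 4 values checked for 1 value far from the other 3, 7 stood out, where chance gives about 3.7. In both-parents embryos the share of egg-enriched transcripts was 1.17% in replicate 2 and 0.476% to 0.531% in the others, a gap of 0.921 of the range. Replicate 2 also stood at 0.901 on the axis from all 24 libraries, against 1.01 to 1.02, a gap of 0.871 of the range. Transcripts longer than 5000 bases took 17.1% in both-parents replicate 3 and 16.1% to 16.2% in the others (0.907 of the range). ENSDART00000145652.3 stood apart in 1 library of that cross (0.920) and ENSDART00000162459.2 in 1 library with BaP-fed mothers (0.902). In eggs of BaP-fed mothers 38389 transcripts had a count in replicate 2, the library with most counts, against 37660 to 37686 (0.964). In control eggs the position on the axis from all 24 libraries was -0.0031 in replicate 3 and -0.0057 to -0.0055 in the others (0.951). The effect of the father differed between the 2 kinds of mother in 278 transcripts by the test of the interaction.

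The egg transcripts in both-parents replicate 2 were weighed as RNA of eggs mixed into the library against slower loss of egg transcripts. Mixing adds the same share of the egg level to every egg transcript. In libraries made by formula without noise, the ratio below was 0.94 for mixing 3 percent egg RNA and 21.9 for slower loss. The median excess over the other 3 replicates was 0.151% of the egg level (quartiles 0 and 0.934%) for 114 transcripts almost lost from them and 4.92% (quartiles 1.41% and 12.7%) for 598 partly lost, a ratio of 32.6. This argues against egg RNA mixed in as the whole excess. In father replicate 4 the median excess was 0 for almost lost and 0.564% for partly lost transcripts, which gives no finite ratio. The quartiles there spanned 0 for almost lost (-0.06% and 0.246%) and for partly lost transcripts (-0.938% and 2.35%). That library therefore cannot show whether a high ratio singles out slower loss, and this was not tested otherwise. Slower loss of egg transcripts may account for the excess in both-parents replicate 2, 1 library of 4. Without this library the maternal count went from 61 to 207 and the interaction from 278 to 422.

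The 128 transcripts lower with only the father BaP-fed were weighed against length bias, embryos nearer to the egg state and reads shared between transcripts. With the length trend removed the median log2 fold change was -0.67 (10th and 90th percentiles -1.07 and -0.45), against -0.73 (-1.06 and -0.53) before. The class of long transcripts had a median log2 fold change of only -0.098 in embryos of BaP-fed fathers. Removing an average trend of that size could not take away a fall of -0.73. The average trend on length was thus smaller than the fall. Length bias that differs between transcripts of similar length was not tested and stays open. In edgeR 83 of the 128 were still called, and the median of the other 45, which were longer (median 6272 bases against 3867), went from -0.62 (10th and 90th percentiles -0.88 and -0.45) to -0.55 (-0.79 and -0.32), and their median adjusted p from 0.0408 to 0.0779. The median adjusted p of the 83 went from 0.0188 to 0.0321, and how far the smaller fold ended the 45 calls was not tested. The shift along the axis from all 24 libraries predicts a median of -0.095, but the bound first set, under which a prediction below 20% of the observed fall counted against this explanation, was replaced after that value was seen, since it assumed a steady pace, and a delay in transcripts that rise late stays open. Shared reads stay open as well, because 2 of the 128 had whole counts, too few to decide. With both parents BaP-fed, the 128 had a median log2 fold change of 0.18 (10th and 90th percentiles -0.03 and 0.31). There 113 were above 0 and 15 below. These values argue against a fall with BaP-fed fathers whatever the mother's diet. An effect of the father's diet with a control mother stays open. It was not tested against the tank, spawning or handling that each cross's libraries may share.

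Other groupings of the libraries tested whether a random split gives as many calls. Only the real grouping did for the 131 calls with only the father BaP-fed (1 of 35 splits as large, highest other 2). The same held for the 61 of the mother's average effect (1 of 100, highest other 2) and the 278 of the interaction (1 of 100, highest other 2). It also held for the 23215 between stages (1 of 35, highest other 0). These are the smallest shares such splits can give, and they were not adjusted over the comparisons. They argue against a random split, but not against a tank, spawning or handling shared by a cross's libraries. A fall with only the father BaP-fed can alone make the maternal and interaction counts stand out. Without single libraries the first 3 counts still ranged from 2 to 189, 2 to 207 and 90 to 422. The lowest father and maternal counts thus equalled the highest of the other splits. Those splits used every library, and none was run with a library left out. How the lowest counts compare with random splits of as few libraries was therefore not tested. Chance cannot be excluded for the 1 call with both parents (5 of 35, highest other 1), the 1 between single-parent crosses (5 of 35, highest other 1) or the 1 of the father's average effect (19 of 100, highest other 1). Any split gives at least the edgeR count of 0 found in eggs (35 of 35, highest other 6, with 1044 at an unadjusted p under 0.05 and 109 by DESeq2) and with BaP-fed mothers (35 of 35, highest other 1, with 1291 and 88), so these splits say nothing of chance.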

How the results depend on the processing

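Whole-count transcripts, removal of the length trend, leaving out 2 libraries together, the axis from all 24 libraries and the axis over all transcripts were chosen after seeing the data. RLE and upper-quartile factors, the effective-length offset and the non-robust dispersion moved no count of calls by over 1.5 times, and the count between stages stayed within 1.5 times under every alternative run on it (19871 to 27006). DESeq2 called 109 (eggs), 284 (both parents), 88 (mother), 828 (father), 1465 (maternal average), 56 (paternal average), 1067 (interaction) and 505 (mother against father). Without a filter the father, maternal and interaction counts were 77, 15 and 151, with more transcripts tested. With the stricter filter the father and maternal counts were 223 and 211 and mother against father 2, with fewer tested. Whole-count transcripts alone (5505 tested) gave 0 for both parents, 1 for the father, 0 for the paternal average, 2 for the interaction and 0 for mother against father, and the maternal 51 shared 8 with the 61. With the length trend removed the father, maternal and interaction counts were 86, 15 and 185. Without both-parents replicate 2 and father replicate 4 the both-parents, maternal and paternal counts were 2, 136 and 2. Fits of only the 8 libraries of the 2 groups gave 3 (both parents), 4 (mother) and 57 (father, 20 higher and 37 lower). Where the number of transcripts or libraries did not change, the cause was not tested. Of the named transcripts' values under alternatives, 248 kept their side of the threshold, 37 lost a call and 13 gained one. Only transcripts called in the main fit can lose a call. Most named transcripts were not called there, so most of the 248 stayed uncalled.

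Without single replicates the counts ranged from 0 to 2 (eggs), 0 to 2 (both parents), 0 to 1 (mother), 2 to 189 (father), 2 to 207 (maternal average), 1 to 2 (paternal average), 90 to 422 (interaction), 1 to 18 (mother against father) and 22936 to 23744 (stages). The egg against embryo correlation ranged from 0.0603 to 0.115 (mother), -0.0399 to 0.0351 (father) and 0.0387 to 0.121 (both parents). It passed against regrouped eggs without control egg replicate 4 (0.115 for mothers, 0.121 for both parents) and, for mothers, without control embryo replicate 4 (0.113). The position difference ranged from -0.0221 to -0.00966 (mother), -0.0545 to -0.0396 (father) and -0.0531 to -0.0131 (both parents). It passed for mothers without mother replicate 3 (-0.0221), and for both parents it no longer passed without control replicate 1 (-0.0448), 2 (-0.0469), 3 (-0.0425) or 4 (-0.0446). For both parents each of these differences was further from 0 than the -0.0419 with all libraries. The position difference was -0.0342 for mothers over all transcripts, where it passed. That axis is drawn from the control libraries, which places other groups lower, so the pass cannot be told apart from this effect. On the axis from all 24 libraries it was -0.0078 for mothers (exact permutation p = 0.486) and -0.0325 for both parents, and neither passed. With controls split in 3 ways the correlations of crosses were 0.035, 0.00748 and 0.0302 (mother and father), 0.0943, 0.0665 and 0.0903 (mother and both) and 0.0381, 0.0119 and 0.0328 (father and both).

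Whether replicate numbers pair the libraries was not settled, as deviations of same-numbered libraries correlated between -0.127 and 0.17. Between mothers and both parents 3 of 4 libraries correlated best with their own number (r of same numbers 0.0594 to 0.17). As many did between controls and both parents (0.0138 to 0.0329). In eggs 2 did, between controls and fathers 1, and in the other pairs of crosses 0. In no pair of groups did every library correlate best with its own number. A replicate block gave 69 (father), 6 (maternal average), 0 (paternal average, edgeR, with 1735 at an unadjusted p under 0.05) and 144 (interaction), and moved no other count by over 1.5 times. The gene list tests, the test without mitochondrial and ribosomal RNA, the list-based developmental score and the correlation over transcripts called in eggs were not run, since no identifier matched a gene name and edgeR called no egg transcript (1044 at an unadjusted p under 0.05, 109 by DESeq2). At the depth and spread of these libraries, edgeR recovered 30 of 100 changes of 2-fold in a simulation of the egg design. The changed transcripts had a mean of at least 2 CPM.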

Other observations

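The test in this part was chosen only after its result was seen. In embryos with only the father BaP-fed, 2 transcripts had no count in all 4 libraries and at least 5 counts in each of the other 12 embryo libraries, and the number was 0 in each of the other 3 crosses. ENSDART00000187324.1 had 26 to 90 counts in the other 12 libraries, and the second transcript had 11 to 122. Of all 1820 sets of 4 embryo libraries, 8 had as many, the real one included, and the highest other number was 2. A variant carried by few parents, a different division of reads between transcripts and the father's diet were not tested against each other.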
